A study of Mus musculus with 29 samples.

How the data were processed

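Poly(A) RNA of 29 tubes of 10 mouse oocytes or zygotes was measured by Smart-seq2, with spike-in RNA added according to the labels' protocol. Libraries were grouped by their labels into 10 groups of genotype (WT or CKO) by stage and age: GO 2W (3 WT and 3 CKO), FGO 3W (2 and 2), FGO 4W (3 and 3), MII 3W (3 and 4) and zygote 3W (3 and 3). The submitters' notes name Trim Galore, FastQC, HISAT2, SAMtools and featureCounts on mm10, without versions, annotation release or strand setting. The deposited counts are raw read counts per gene symbol for 49997 genes, with no normalization by the authors. Of the counts from 1 to 20, 81% were even, so both ends of a read pair appear to have been counted. The deposited FPKM, computed by the authors, equal the count divided by gene length and by the library's total counted reads, up to a constant, checked on 8052 genes with at least 50 counts in each library to a relative tolerance of 1e-09. The count table held 0 spike-in genes and 0 mitochondrially encoded mRNAs, so the planned ratio to spike-in reads and spike-in size factors were not run. Totals per library ran from 17697507 to 49104313 counts, and from 14691 to 19890 genes had at least 10 counts. Reads carry no molecular identifiers, so a floor of 3 counts covers counting error only.

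Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM size factors, the filterByExpr filter by group (minimum count 10, leaving 21768 genes), 1 model of all 10 groups and quasi-likelihood F tests with 19 residual and 8.308 prior degrees of freedom. Fold changes were those of the fit with edgeR's default prior count, log2 CPM used a prior count of 2, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. Dispersions followed a trend over expression (0.0337 to 1.17), a setting chosen after the data had been examined. On simulated data with the groups and depths of this series, 1 dispersion for all genes called 200 of 21509 unchanged genes at FGO 3W and gave 11.7% of them an unadjusted p under 0.05, against 1 gene and 4.95% with the trend. The simulated counts were drawn from that same trend, with no spread of single genes around it. The trend's result there was thus given by the setting and cannot show that it suits the real data. The shares of simulated changes called hold for this setting only. In simulated data, 2-fold changes were called in 22.4%, 10.4%, 26.9%, 37.3% and 38.8% of changed genes at GO 2W, FGO 3W, FGO 4W, MII 3W and zygote 3W, and 4-fold changes in 78.8%, 62.1%, 87.9%, 95.5% and 87.9%. No label says that replicates came from separate animals, so p-values measure the spread between samples. That spread was estimated for each gene over all 10 groups together, although groups varied unequally. Replicate pairs correlated at 0.9019 to 0.9315 in CKO zygotes and 0.9597 to 0.9631 in WT zygotes. At MII they correlated at 0.9494 to 0.9772 in CKO and 0.9757 to 0.9776 in WT. For groups that varied more than the others, the edgeR p-values may be too small.

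The comparisons were CKO against WT at each of 5 stages, the difference of that change between stages, and WT stages against each other. Stage, age and any unlabelled batch cannot be separated in the comparisons between stages. Named genes were Dhx36, for each stage the 8 highest and 8 lowest changes among called genes with at least 5 CPM in the higher group, ranges apart and no predicted name, and up to 4 members of each list with the smallest adjusted p. For the other contrasts 5 and 5 genes were taken. Genes named because they changed at all 5 stages, beyond this rule, were chosen after their values were seen. Fold changes against a group at 0 are given as "at least" values against 3 counts over the group. If both ends of a pair were counted, 3 counts stand for fewer than 3 read pairs, so these values may be too high. Dhx36 was also tested by exact two-sided permutation of libraries within stages.

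Lists of related genes were tested with limma 3.58.1 camera on log2 CPM at a preset correlation between genes of 0.01, with p adjusted over 100 tests of 20 lists. Of these 20 were called, and 0 of the 20 with the correlation estimated from the data, while limma fry called 33 and ended 2 of the 20 calls. Each p given below for a list with an estimated correlation is adjusted over the same tests. Genes at least 2-fold changed between WT stages were tested the same way in contrasts that do not share their WT libraries, in 12 tests. Gene symbols were matched to the RefSeq gene table of GRCm38, where 100% of the tested symbols were found, and transcript sequences came from GENCODE vM21. G-quadruplex motifs (4 runs of at least 3 G with loops of 1 to 7 bases) were searched on the sense strand of 1 transcript per gene in 14753 genes, with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. Each library's log2 CPM, centred within its stage, was regressed on motif presence with GC content, length and expression as covariates, and CKO and WT coefficients were compared by exact permutation.

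Alternatives were RLE size factors, no filter and a stricter filter, DESeq2 1.42.0, each stage fitted alone, a replicate block, limma on log2 FPKM with pseudocounts of 1 and 0.1, fry, a 4-fold list threshold, other motif settings and leaving out each library in turn. Added after the data had been examined were 1 dispersion for all genes, leaving out 3 libraries rich in ribosomal RNA (CKO MII replicates 2 and 3, CKO zygote replicate 1) and leaving out these and CKO zygote replicate 3, which held blood cell markers. Leaving out each library in the list tests, leaving out libraries in the motif tests by region, and the alternatives for the correlation between stages were added then too. Where 1 library of a group remained, it was assumed to vary like the other groups. Replicate numbers did not pair WT with CKO libraries: the 14 same-numbered pairs correlated from -0.0797 to 0.0392 after centring.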

Results

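The series measured poly(A) RNA by Smart-seq2 in mouse oocytes and zygotes that lack, by their labels, the G-quadruplex helicase gene Dhx36 in the female germ line (CKO, Dhx36 fl/fl with Zp3-Cre), beside Dhx36 fl/fl controls (WT). Each of the 29 libraries was made from a tube of 10 cells. Growing oocytes of 2-week-old females (GO 2W), fully grown oocytes of 4-week-old females (FGO 4W) and zygotes of 3-week-old females (zygote 3W) had 3 WT and 3 CKO libraries each. Fully grown oocytes of 3-week-old females (FGO 3W) had 2 and 2, and metaphase II oocytes of 3-week-old females (MII 3W) had 3 WT and 4 CKO. Counts per library totalled between 17697507 and 49104313. Levels are CPM, counts scaled to a common library total, as mean and SD over libraries, changes are log2 of CKO over WT with their SE, and called means an edgeR adjusted p under 0.05.

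The first comparison asked whether Dhx36 itself was lower in CKO-labelled libraries. Whole-gene Dhx36 counts (chromosome 3, 62468015 to 62507034, GRCm38) were not lower in CKO at any of the 5 stages. At MII 3W they averaged 412.0 CPM (SD 16, n = 3) in WT and 1426 CPM (SD 1290, n = 4) in CKO, a change of 1.79 (SE 0.434, adjusted p 0.00197), which was 1.03 without CKO replicate 1. An exact two-sided permutation test of Dhx36 at MII 3W gave p = 0.257, and over the 5 stages together the mean difference of log2 CPM was 0.50 (exact permutation p 0.0165). The changes at GO 2W, FGO 3W, FGO 4W and zygote 3W were 0.12, 0.40, 0.31 and 0.44, with adjusted p of 0.901, 0.675, 0.655 and 0.494. The GO 2W value was -0.050 without CKO replicate 3, and the zygote value was -0.14 without CKO replicate 1. The labels do not say which exons the deletion removes, so a count over the whole gene cannot check the genotype labels.

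**Figure D1:**
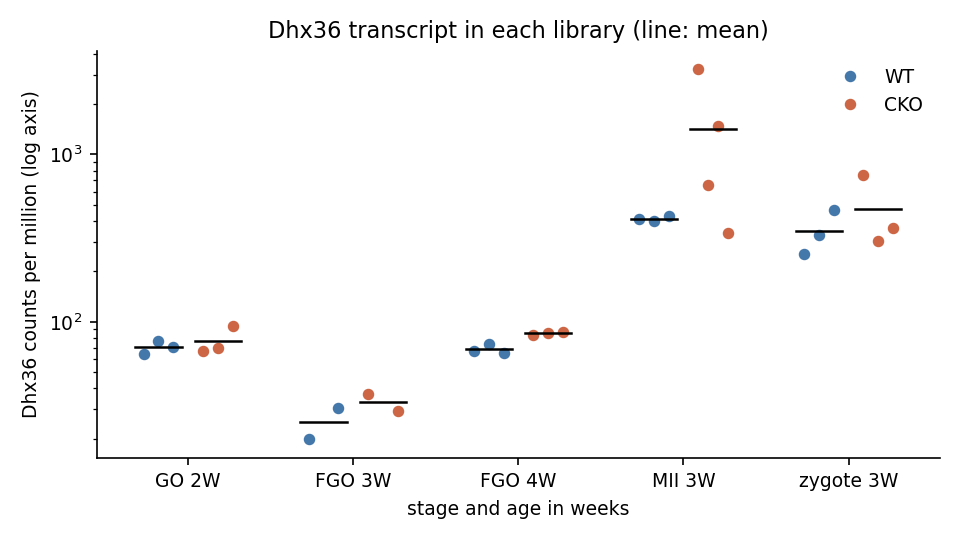
Dhx36 level in each of the 29 libraries, in CPM on a log axis, by stage and genotype; points are libraries and lines are group means. The 4 CKO libraries at MII 3W lie at 3226, 660.4, 1478 and 338.3 CPM, beside a WT mean of 412.0.

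Many genes changed in the same direction at every stage. Sohlh1, which encodes a transcription factor of early oocyte growth, was higher in CKO at all 5 stages (6.85 at GO 2W, 6.22 at FGO 4W and 7.22 at zygote 3W). Tcstv3, a gene of a 2-cell-stage family, was higher by 2.05, 2.59, 2.85, 3.88 and 3.13 from GO 2W to zygote 3W. Eif4ebp1, which encodes the cap-binding inhibitor 4E-BP1, was higher by 3.68, 2.85, 2.64, 3.54 and 3.21. Dclk1, a microtubule-associated kinase gene, was lower by between -7.58 and -5.07, and the alpha-tubulin gene Tuba3b by between -8.25 and -2.09. Btg4, whose product brings the CCR4-NOT deadenylase to maternal mRNA, was lower by -0.64, -0.90, -0.89, -0.79 and -0.48. In all, 372 genes were higher at all 5 stages, where independent stages would give 0.409, and 261 were lower, where they would give 0.362. Changes of all genes correlated between stage pairs with Pearson r from 0.237 to 0.401 (mean 0.303 of 10 pairs, and 0.181 with no low-count filter), across genes that are not independent replicates.

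**Figure D2:**
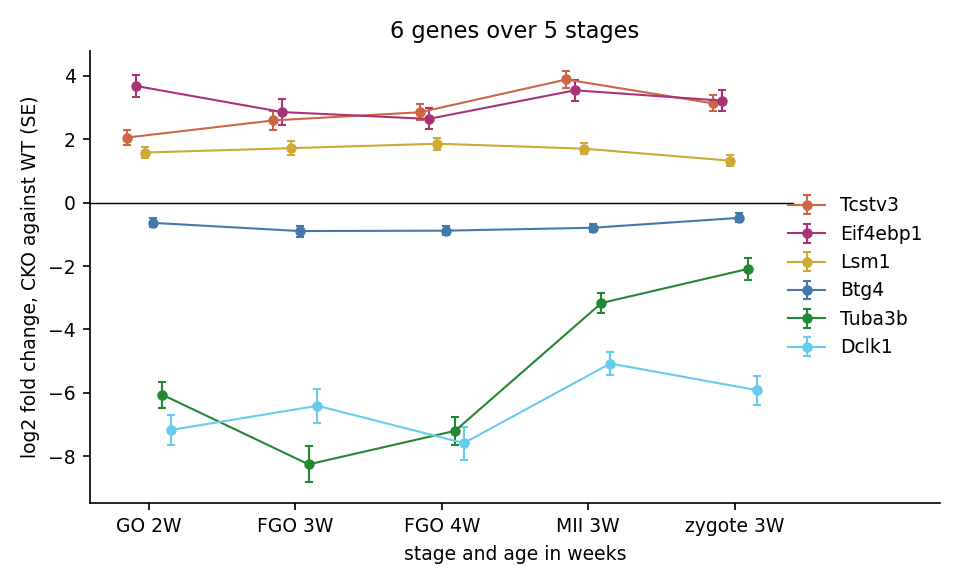
Log2 fold change (CKO over WT) of Tcstv3, Eif4ebp1, Lsm1, Btg4, Tuba3b and Dclk1 at the 5 stages; points are edgeR estimates and bars their SE. Tcstv3, Eif4ebp1 and Lsm1 lie above 0 and Btg4, Tuba3b and Dclk1 below 0 at each stage.

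In GRCm38, Sohlh1 lies on chromosome 2 from 25842995 to 25847248, Tcstv3 on chromosome 13 from 120316862 to 120318261, and Eif4ebp1 on chromosome 8 from 27260327 to 27275656. Dclk1 lies on chromosome 3 from 55242303 to 55539068, Tuba3b on chromosome 6 from 145615963 to 145621477, and Btg4 on chromosome 9 from 51102147 to 51119924. Members of the Tcstv, Dcpp, Defb, Pramel, Usp17l, Obox and Xlr families share sequence, so that a read may be counted for a copy other than its source.

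**Figure D3:**
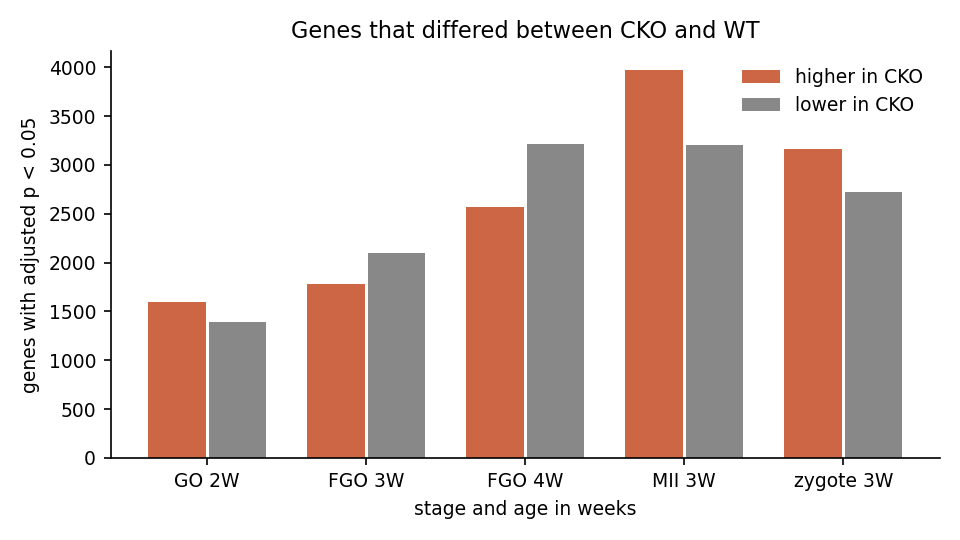
Number of genes called higher and lower in CKO at each stage among 21768 tested genes (bars from 0). At GO 2W 1597 genes were higher and 1388 lower, the fewest of each, against 3971 and 3201 at MII 3W. The most lower genes, 3215, were called at FGO 4W.

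The GO 2W comparison asked what had changed during oocyte growth, with 3 libraries per genotype. Sohlh1 averaged 24.0 CPM (SD 15.1) in CKO and 0.204 (SD 0.0656) in WT (6.85, SE 0.67, adjusted p 8.52e-08). Dclk1 averaged 0.306 CPM (SD 0.139) in CKO and 43.9 (SD 1.74) in WT (-7.17, SE 0.482, adjusted p 1.17e-10). Eif2ak3, which encodes the endoplasmic reticulum stress kinase PERK, was higher by 2.62 (SE 0.257, adjusted p 8.52e-08), at 38.0 against 6.16 CPM. The chaperone genes Calr, Dnajc3 and Pdia4 were lower by -1.62, -1.12 and -1.16, Calr from 551.1 CPM (SD 30) to 179.6 (SD 6.17). Of 33 tested integrated stress and unfolded protein response genes 5 were higher, 8 lower and 20 not called, and their list was not called. The defensin Defb48 was at least 226-fold higher and the potassium channel gene Kcnh8 at least 291-fold lower, against a floor of 3 counts over the group. Such bounds, here and below, may be too high, as both ends of a read pair appear to have been counted.

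Among all genes at GO 2W, 1597 were higher and 1388 lower, 1245 and 694 of them at least 2-fold. The higher count was 1054, 941 and 1002 without WT replicate 1, WT replicate 2 and CKO replicate 3. The lower count was 919, 902, 799 and 722 without WT replicate 1, WT replicate 2, CKO replicate 1 and CKO replicate 3. A fit of this stage alone called 3520 and 2827. With limma on log2(FPKM + 1), which also changes the test and filter, 69.6% of the called genes were higher, against 53.5% in the main fit. The ranges of WT and CKO were apart in 2957 of the called genes and in 44% of all genes, where chance gives 10%.

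Some lists of related genes were lower as lists at GO 2W by camera. Several lists that were not called had medians as low. These were -0.227 for oocyte transcription factor and zona genes, for the subcortical maternal complex and for maternal-effect chromatin genes, and -0.226 for translation factors. Others lay higher, such as zygotic genome activation (0.432) and mRNA decay genes (-0.0575). A low median was thus not particular to the called lists. Of 56 meiotic resumption, spindle and metaphase II arrest genes 2 were higher, 9 lower and 45 not called (2 and 9 adjusted over the list alone), with a median of -0.26 and adjusted p 0.0115. Its adjusted p was 0.621 with an estimated correlation between genes. For the other lists too, the p with an estimated correlation is the adjusted one. The list held the securin gene Pttg1 (-0.85, from 1745 to 966.7 CPM), Fbxo43, whose product holds the metaphase II arrest (-0.79), and Gpr3, which keeps the meiotic arrest (-0.89). Of 63 nucleolus, RNA polymerase I and ribosome biogenesis genes 2 were higher, 12 lower and 49 not called (4 and 13 adjusted over the list alone), with a median of -0.23, adjusted p 0.0321 and p 0.32 with an estimated correlation. Polr1a, the largest subunit of RNA polymerase I, was lower by -1.02 and Bysl, needed for the small ribosomal subunit, by -1.17. Of 45 RNA polymerase II and splicing genes 3 were higher, 7 lower and 35 not called (3 and 8 adjusted over the list alone), with a median of -0.20, adjusted p 0.0267 and p 0.357 with an estimated correlation. The calls of the nucleolus and RNA polymerase II lists ended in a fit of this stage alone. Of 81 cytoplasmic ribosomal protein genes 0 were higher, 4 lower and 77 not called (0 and 0 adjusted over the list alone), with a median of -0.23, adjusted p 0.0376 and p 0.841 with an estimated correlation, and its call also ended without the 3 libraries rich in ribosomal RNA. Of 77 nuclear-encoded oxidative phosphorylation genes 1 was higher, 4 lower and 72 not called (1 and 3 adjusted over the list alone), with a median of -0.21, adjusted p 0.0221 and p 0.781 with an estimated correlation. The test fry called neither of these last 2 lists (adjusted p 0.255 for ribosomal protein and 0.146 for oxidative phosphorylation genes). The main fit gave a median of all genes of -0.013. With limma on log2(FPKM + 1), over 15242 genes and another filter, it was 0.069, and 0.096 with a pseudocount of 0.1. At FGO 3W and FGO 4W it was 0.090 and 0.087 with a pseudocount of 1, and 0.12 at both with 0.1. As differences of mean log2(FPKM + 1), the ribosomal, meiotic, nucleolus, oxidative phosphorylation and RNA polymerase II medians were -0.054, -0.079, -0.052, -0.042 and -0.033. All 20 called list medians kept their sign under RLE size factors and FPKM. At FGO 3W, as differences of mean log2 values, they shrank under log2(FPKM + 1), from -0.32 to -0.050 for oxidative phosphorylation, -0.35 to -0.076 for translation, -0.37 to -0.10 for meiotic, -0.43 to -0.17 for RNA polymerase II and -0.49 to -0.22 for ribosomal protein genes.

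The FGO 3W comparison, with 2 libraries per genotype, asked the same of fully grown oocytes at 3 weeks. Pramel27, of a germ-cell-expressed family, averaged 622.8 CPM (SD 23.2) in CKO and 0.523 (SD 0.0982) in WT (10.21, SE 0.929, adjusted p 2.9e-08). Xdh, which encodes xanthine dehydrogenase, averaged 103.1 CPM (SD 4.48) and 0.235 (SD 0.221; 8.76, SE 1.09, adjusted p 3.5e-06). Obox2, an oocyte-specific homeobox gene of the zygotic genome activation list, averaged 20.9 CPM (SD 0.956) in CKO and 1643 (SD 472) in WT (-6.30, SE 0.791, adjusted p 3.93e-06). The zona-cleaving protease gene Astl fell from 969.0 CPM (SD 35.8) to 417.4 (SD 23.8). The metallothionein Mt1 was higher by 7.52, the serine protease gene Prss35 at least 527-fold lower and the cystatin gene Cst9 at least 358-fold higher. In WT, Pramel27, Xdh and Mt1 averaged 172.2, 71.8 and 127.5 CPM at GO 2W, against 0.523, 0.235 and 0.674 at FGO 3W. Their changes at FGO 3W thus came with a WT level far below that of WT GO 2W.

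At FGO 3W 1782 genes were higher and 2095 lower, 1552 and 1309 of them at least 2-fold, with SDs from pairs of libraries. Without WT replicate 1, WT replicate 2, CKO replicate 1 and CKO replicate 2 in turn, 828, 905, 970 and 984 were higher and 976, 1333, 894 and 838 lower. A fit of this stage alone called 3860 higher, and 1 dispersion for all genes gave 3538 higher and 3317 lower. Which direction held more genes depended on the scaling, with 1895 higher and 1805 lower under RLE size factors. With limma on log2(FPKM + 1), which also changes the test and filter, it was 3207 and 1457. The ranges were apart in 3876 of the called genes and in 69% of all genes, where chance gives 33.3%.

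The FGO 3W lists called lower in CKO were the meiotic, ribosomal protein, translation, oxidative phosphorylation and RNA polymerase II genes. Several lists that were not called had medians as low. These were the oocyte transcription factor and zona (-0.505), mRNA decay (-0.493), p53 (-0.409) and maternal-effect chromatin genes (-0.381). The zygotic genome activation list lay above 0 (0.125). A low median was thus not particular to the called lists. Of 56 meiotic genes 2 were higher, 15 lower and 39 not called (2 and 17 adjusted over the list alone), with a median of -0.38, adjusted p 0.000936 and p 0.501 with an estimated correlation. Fbxo5, an inhibitor of the anaphase-promoting complex, fell from 223.2 CPM (SD 42.1) to 99.2 (SD 2.4), and Cdc20, its activator, by -1.47. Of 81 ribosomal protein genes 2 were higher, 12 lower and 67 not called (2 and 12 adjusted over the list alone), with a median of -0.49, adjusted p 0.00197 and p 0.676 with an estimated correlation, including Rpl30 (-1.78) and Rpl13 (-1.17). Of 44 translation factor genes 1 was higher, 8 lower and 35 not called (1 and 8 adjusted over the list alone), with a median of -0.36, adjusted p 0.0321 and p 0.605 with an estimated correlation. Eef2, the elongation factor gene, was lower by -1.21 and its kinase gene Eef2k by -1.33, and a fit of this stage alone ended the list's call. Of 77 oxidative phosphorylation genes 1 was higher, 11 lower and 65 not called (1 and 10 adjusted over the list alone), with a median of -0.32, adjusted p 0.00288 and p 0.63 with an estimated correlation. The complex I genes Ndufb5 and Ndufs4 were lower by -1.12 and -1.05, while Uqcrc1 of complex III was higher by 2.71. Of 45 RNA polymerase II and splicing genes 3 were higher, 11 lower and 31 not called (4 and 14 adjusted over the list alone), with a median of -0.46, adjusted p 0.0106 and p 0.296 with an estimated correlation, including the polymerase subunit gene Polr2k (-1.44).

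The FGO 4W comparison asked the same at 4 weeks, with 3 libraries per genotype. Ddx6, which encodes an RNA helicase of mRNA storage and decay granules, averaged 47.9 CPM (SD 4.75) in CKO and 3.9 (SD 1.18) in WT (3.62, SE 0.329, adjusted p 9.1e-09). Astl averaged 136.3 CPM (SD 42.9) in CKO and 949.4 (SD 152) in WT (-2.80, SE 0.231, adjusted p 2.1e-09). The potassium channel gene Kcng2 averaged 57.4 CPM (SD 9.55) and 0.566 (SD 0.488; 6.65, SE 0.588, adjusted p 5.18e-09). Dnmt3a, the DNA methyltransferase of growing oocytes, fell from 283.7 CPM (SD 16) to 141.9 (SD 9.03). The hormone gene Fgf21 was higher by 6.60, and the sperm-associated gene Iqcf1 was at least 265-fold lower.

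At FGO 4W 2567 genes were higher and 3215 lower, 1989 and 1909 of them at least 2-fold, and the ranges were apart in 5507 called genes and in 46.7% of all genes, where chance gives 10%. RLE size factors gave 2778 higher and 2903 lower, while limma on FPKM, which also changes the test and filter, gave 3560 and 2452 with a pseudocount of 1 and 3168 and 2224 with 0.1. Of 22 oocyte transcription factor and zona or secreted protein genes 2 were higher, 13 lower and 7 not called (2 and 13 adjusted over the list alone), with a median of -0.56, adjusted p 0.0071 and p 0.378 with an estimated correlation, including Kit (-0.86) and Lhx8 (-1.11). Of 15 subcortical maternal complex and cytoplasmic lattice genes 0 were higher, 8 lower and 7 not called (0 and 9 adjusted over the list alone), with a median of -0.61, adjusted p 0.0351 and p 0.605 with an estimated correlation. Its members Ooep, Tle6 and Nlrp9b were lower by -0.71, -1.01 and -0.97. Of 56 meiotic genes 1 was higher, 23 lower and 32 not called (5 and 28 adjusted over the list alone), with a median of -0.37, adjusted p 0.00488 and p 0.605 with an estimated correlation, including the cohesin gene Smc1b (-1.93) and Fbxo43 (-1.04). Of 38 zygotic genome activation genes 12 were higher, 4 lower and 22 not called (18 and 6 adjusted over the list alone), with a median of 1.21, adjusted p 0.00496 and p 0.501 with an estimated correlation. Tcstv3 rose from 16.1 CPM (SD 3.3) to 115.6 (SD 12.6), Nr5a2 was higher by 1.01, and a fit of this stage alone ended the call of this list. As differences of mean log2 values, these 4 medians shrank under log2(FPKM + 1), from -0.56 to -0.37 for the oocyte factors, -0.63 to -0.43 for the maternal complex, -0.37 to -0.18 for meiotic and 1.08 to 0.58 for zygotic genome activation genes.

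The MII 3W comparison, with 3 WT and 4 CKO libraries, asked what differed after meiotic maturation. Rps13, a small-subunit ribosomal protein gene (chromosome 7, 116331507 to 116334190), averaged 73.1 CPM (SD 18.1) in CKO and 5.99 (SD 1.35) in WT (3.61, SE 0.314, adjusted p 1.6e-09). Ndufa2 of respiratory complex I averaged 31.0 CPM (SD 8.08) and 2.87 (SD 0.369; 3.43, SE 0.231, adjusted p 2.12e-11). Cdc5l, a splicing factor gene (chromosome 17, 45391887 to 45433707), averaged 0.116 CPM (SD 0.0603) in CKO and 59.7 (SD 22.2) in WT (-9.03, SE 0.685, adjusted p 1.86e-10). The meiotic chromosome axis gene Hormad1 averaged 1.33 CPM (SD 0.668) and 54.9 (SD 4.43; -5.35, SE 0.421, adjusted p 2.91e-10). Zbed3, of the subcortical maternal complex, fell from 32680 CPM (SD 3550) to 13850 (SD 3210).

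The ribosomal protein and oxidative phosphorylation genes were higher as lists at MII 3W. Of 81 ribosomal protein genes 55 were higher, 4 lower and 22 not called (57 and 4 adjusted over the list alone), with a median of 1.41, adjusted p 3.61e-17 and p 0.296 with an estimated correlation. Of 77 oxidative phosphorylation genes 53 were higher, 7 lower and 17 not called (54 and 8 adjusted over the list alone), with a median of 1.31, adjusted p 2.01e-12 and p 0.296 with an estimated correlation. Atp5a1, an ATP synthase gene, went the other way (-1.71, SE 0.118, adjusted p 3.39e-11). The ribosomal protein genes' mean log2 CPM per library lay between 2.75 and 2.84 in WT MII, between 3.98 and 4.73 in CKO MII and between 6.52 and 6.66 in WT GO 2W. The ribosomal RNA-related gene Rn18s-rs5 took 21.9% and 8.43% of the counts of CKO MII replicates 3 and 2. Without those libraries and CKO zygote replicate 1 the medians were 1.27 and 1.16, and 51 and 55 genes were higher. Of 56 meiotic genes 12 were higher, 26 lower and 18 not called (13 and 28 adjusted over the list alone), with a median of -0.43, adjusted p 0.0267 and p 0.63 with an estimated correlation. The kinase gene Plk1 was lower by -1.06 (SE 0.11) and Fbxo43 by -1.27, and this list's call ended in a fit of the stage alone and without the 3 libraries rich in ribosomal RNA. Its median shrank from -0.47 to -0.21 under log2(FPKM + 1), as differences of mean log2 values.

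Among all genes at MII 3W, 3971 were higher and 3201 lower, 3090 and 1555 of them at least 2-fold, and without the 3 libraries rich in ribosomal RNA 3431 and 3042. The ranges were apart in 6378 called genes and in 37.5% of all genes, where chance gives 5.71%. With limma on log2 FPKM, over 15242 genes and another filter, the median of all genes depended on the pseudocount. It was 0.10 with a pseudocount of 1 and 0.21 with 0.1, against 0.13 in the main fit. Of the called genes 64.3% were higher with a pseudocount of 1, against 55.4% in the main fit.

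**Figure D4:**
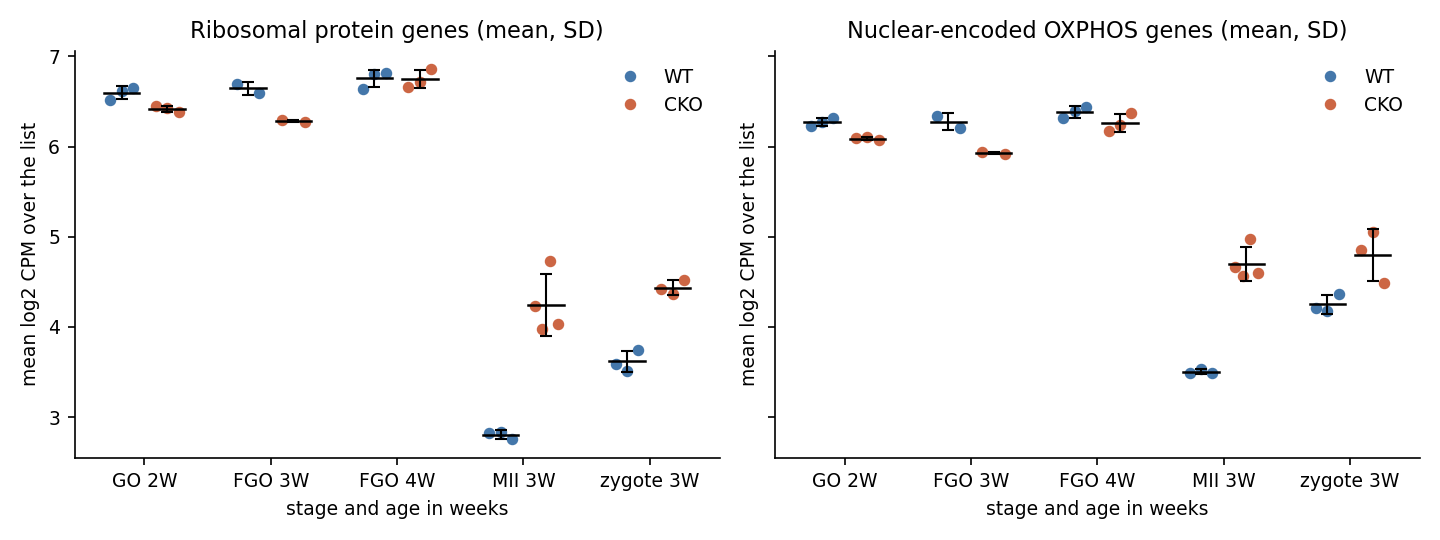
Mean log2 CPM of the ribosomal protein genes and of the oxidative phosphorylation genes in each library, by stage and genotype; points are libraries, lines are group means and bars are SDs. At MII 3W the CKO libraries lie between 3.98 and 4.73 for the ribosomal protein genes and the WT libraries between 2.75 and 2.84.

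The zygote 3W comparison asked which transcripts differed after fertilization of CKO-labelled oocytes, with 3 libraries per genotype. Ptgfrn, a membrane protein gene (chromosome 3, 101040230 to 101110745), averaged 89.3 CPM (SD 9.06) in CKO and 1.54 (SD 0.786) in WT (5.84, SE 0.482, adjusted p 2.09e-09). Rplp1, a ribosomal stalk gene, averaged 121.1 CPM (SD 71.7) and 6.54 (SD 0.396; 4.21, SE 0.33, adjusted p 1e-09). Uhrf1, needed for maintenance of DNA methylation, rose from 459.7 CPM (SD 67.9) to 1109 (SD 143). The growth factor gene Bmp15 fell from 6706 CPM (SD 564) to 2915 (SD 651). Ooep averaged 298.9 CPM (SD 60.7) in CKO and 914.7 (SD 106) in WT (-1.61, SE 0.149, adjusted p 9.7e-09). At MII 3W Ooep was higher in CKO.

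At zygote 3W 3162 genes were higher and 2719 lower, 2265 and 1670 of them at least 2-fold. Rn18s-rs5 took 27.3% of the counts of CKO replicate 1, and blood cell markers summed to 114 CPM in CKO replicate 3 against at most 9.41 in any other library. Without these and the CKO MII replicates rich in ribosomal RNA, the median of all genes was -0.16, with only CKO zygote replicate 2 left in its group. A fit of this stage alone called 1112 and 988. With limma on log2(FPKM + 1) fewer were higher (2035) than lower (3431). The ranges were apart in 4856 called genes and in 30.3% of all genes, where chance gives 10%. Of 81 ribosomal protein genes 36 were higher, 7 lower and 38 not called (38 and 7 adjusted over the list alone), with a median of 0.56, adjusted p 4.2e-06 and p 0.605 with an estimated correlation. Without the 4 libraries in doubt, which leaves only CKO zygote replicate 2 in its group, this median was 0.089. Of 77 oxidative phosphorylation genes 36 were higher, 11 lower and 30 not called (41 and 14 adjusted over the list alone), with a median of 0.58, adjusted p 0.00503 and p 0.664 with an estimated correlation. This call ended without the 3 libraries rich in ribosomal RNA, where the median was 0.42 with 37 higher and 18 lower. Without the 4 in doubt the median was 0.58. Of 44 translation factor genes 6 were higher, 13 lower and 25 not called (6 and 16 adjusted over the list alone), with a median of -0.28, adjusted p 0.0483 and p 0.605 with an estimated correlation. Eif2s1, which encodes the initiation factor subunit eIF2-alpha, was lower by -1.97 and Eef1a1 by -2.04, and a fit of this stage alone ended the list's call. With limma on log2 FPKM, over 15242 genes and another filter, the median of all genes went from 0.078 to below 0. It was -0.062 with a pseudocount of 1 and -0.13 with 0.1. As differences of mean log2(FPKM + 1), the ribosomal protein and oxidative phosphorylation medians stayed above 0, at 0.23 and 0.36.

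Genes that handle maternal mRNA changed in both directions, and neither list was called at any stage. Lsm1, of the cytoplasmic decapping complex, was higher by 1.58, 1.72, 1.86, 1.70 and 1.32 from GO 2W to zygote 3W, from 47.9 CPM (SD 7.54) to 142.9 (SD 23.7) at GO 2W. Dcp1a, a decapping cofactor gene, fell from 2833 CPM (SD 64.2) to 1374 (SD 202) at MII 3W and was higher by 1.28 in zygotes. The exosome gene Exosc9 was lower by -2.19 at FGO 4W. Of 43 deadenylation and decay genes 3, 3, 7, 10 and 12 were higher and 5, 7, 5, 14 and 8 lower from GO 2W to zygote 3W. Of 33 mRNA storage and polyadenylation genes 3, 4, 4, 7 and 6 were higher and 4, 9, 12, 8 and 6 lower. Ybx2, which encodes an oocyte mRNA-binding protein, was higher by 3.44 at MII 3W, from 11.2 CPM (SD 1.31) to 121.9 (SD 74.5). Eif4enif1, a translational repressor gene, was lower by -0.75, -1.01 and -0.62 at FGO 4W, MII 3W and zygote 3W.

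Of 38 G-quadruplex helicase and binding protein genes other than Dhx36, 4, 5, 6, 8 and 10 were higher and 5, 7, 6, 10 and 7 lower from GO 2W to zygote 3W, and the list was not called. Fmr1, whose product binds G-quadruplex RNA, was higher by 1.16, 2.20, 1.95 and 1.95 from GO 2W to MII 3W. Dna2, a helicase and nuclease gene, was lower by -1.44 and -1.17 at FGO 4W and MII 3W. Of 33 maternal-effect chromatin genes 3, 4, 5, 9 and 10 were higher and 6, 6, 4, 4 and 3 lower, with the H3K36 methyltransferase gene Nsd1 lower by -1.03, -1.01 and -0.77 from GO 2W to FGO 4W. Of the stress response genes 4, 7, 9 and 6 were higher and 8, 6, 9 and 7 lower from FGO 3W to zygote 3W, with Pdia4 lower by -2.52 (SE 0.17, adjusted p 2.29e-10) in zygotes. Of 31 p53 and DNA damage genes 3, 2, 1, 3 and 3 were higher and 1, 5, 6, 8 and 5 lower, with the histone gene H2ax higher by 1.10 at MII 3W and 2.23 in zygotes. Of 21 interferon response genes 0, 0, 1, 1 and 4 were higher and 1, 1, 3, 0 and 2 lower, with the RNA sensor gene Ddx58 lower by -1.51, -1.42 and -2.12 at GO 2W, FGO 4W and zygote 3W. Of the zygotic genome activation genes 8, 5, 8 and 7 were higher and 2, 4, 3 and 4 lower at the stages other than FGO 4W. None of the 13 mitochondrially encoded mRNAs was in the table. Median and mean differed in sign for several lists that were not called, as for the oocyte transcription factors at MII 3W (median -0.30, mean 0.42) and mRNA decay at MII 3W (median -0.16, mean 0.12).

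Marker genes of other cells were tested as 4 lists, none called. Fshr, the follicle-stimulating hormone receptor gene of granulosa cells, was higher by 3.91 at FGO 4W, from 1.35 CPM (SD 0.962) to 20.3 (SD 4.83). Of 21 granulosa and cumulus genes 3, 2, 2, 3 and 5 were higher and 0, 1, 1, 0 and 1 lower from GO 2W to zygote 3W. Their sum was 375 CPM (SD 29.8) in WT and 526 (SD 24.3) in CKO at GO 2W, 418.5 (SD 40.3) and 551 (SD 4.24) in fully grown oocytes at 3 weeks, 510.3 (SD 28.9) and 633.7 (SD 28.7) at 4 weeks, 799.7 (SD 10.8) and 732.2 (SD 185) at MII 3W, and in zygotes 440.7 (SD 31.5) and 303.0 (SD 106). Of 8 blood and immune cell genes 5 were higher in zygotes, 7 adjusted over the list alone, where Ptprc was at least 79.4-fold higher, and at GO 2W and FGO 4W 1 was higher. In zygotes the calls of the immune cell genes Lyz2 and Cd74 ended without CKO replicate 3, the library with 114 CPM of these markers. Of 8 theca and stroma genes 1, 0, 0, 1 and 1 were higher and 0, 0, 2, 0 and 1 lower. Of 9 sperm genes 1, 1, 1, 1 and 0 were higher and 0, 0, 0, 1 and 1 lower. Their sum was 34.97 CPM (SD 8.54) in WT and 121.3 (SD 22) in CKO at GO 2W, 28.2 (SD 10.5) and 83.9 (SD 8.06) in fully grown oocytes at 3 weeks and 24.13 (SD 10.5) and 46.47 (SD 9.22) at 4 weeks, stages before any contact with sperm. The median change of the list at these stages was -0.195, -0.348 and 0.476, so the higher sums at GO 2W and FGO 3W were not shared by most members.

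Next, the CKO change was compared between stages, to ask which changes belonged to a stage. Pramel27 changed by 0.37 at GO 2W and 10.21 at FGO 3W (difference 9.83, SE 0.991, adjusted p 2.93e-07), and Gpat3, of triglyceride synthesis, by -6.28 and 3.42 (difference 9.69, SE 0.985, adjusted p 2.97e-07). Pramel27 averaged 172.2 CPM in WT GO 2W and 0.523 in WT FGO 3W, so its difference came with a lower WT level. Cdc5l differed by 9.68 between MII 3W and zygote 3W (adjusted p 3.02e-07). The change differed in 364 genes between GO 2W and FGO 3W, 592 between FGO 3W and FGO 4W, 3205 between FGO 3W and MII 3W and 3415 between MII 3W and zygote 3W. The first count was 210, 241, 201 and 189 and the next was 306, 305, 298 and 302 without WT FGO 3W replicate 1, WT FGO 3W replicate 2, CKO FGO 3W replicate 1 and CKO FGO 3W replicate 2. The count of 3205 was 1648, 1708 and 1529 without WT FGO 3W replicate 2, CKO FGO 3W replicate 1 and CKO FGO 3W replicate 2, and that of 3415 was 5164 without CKO zygote replicate 1. The ribosomal protein list moved up by 1.83 between FGO 3W and MII 3W (adjusted p 9.25e-27) and the oxidative phosphorylation list by 1.66 (adjusted p 2e-20), but none of the 8 list differences called among 80 tests was called with an estimated correlation.

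The WT stages were compared with each other, where stage, age and any unlabelled batch cannot be separated. Some WT levels fell and returned. At GO 2W, FGO 3W, MII 3W and zygote 3W, Pramel27 averaged 172.2, 0.523, 0.029 and 167.2 CPM, and Mt1 127.5, 0.674, 0.452 and 44.9. Between GO 2W and FGO 3W, Manba, a lysosomal enzyme gene, was higher by 8.76 and Xdh lower by -8.24. In all 227 genes changed, and 124, 148, 82 and 111 without WT GO 2W replicate 1, WT GO 2W replicate 2, WT FGO 3W replicate 1 and WT FGO 3W replicate 2. From FGO 3W to MII 3W 4307 genes were higher and 6199 lower, and from MII 3W to zygote 3W 4198 and 3198. Mos, the kinase gene that holds the metaphase II arrest, went from 722.7 CPM (SD 111) in WT MII oocytes to 28.4 (SD 2.82) in WT zygotes (-4.67, SE 0.293, adjusted p 2.2e-12).

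To ask whether differences between WT stages were altered in CKO, genes that change at least 2-fold between WT stages were tested as lists. Of the 3433 genes lower in WT zygotes than in WT FGO 4W, 1220 were higher and 329 lower in CKO MII oocytes. Their median was 0.55 and the camera adjusted p 7.69e-07 (adjusted p 0.000261 with an estimated correlation). Of the 5693 genes lower in WT MII than in WT FGO 3W, 696 were higher and 1349 lower in CKO zygotes. Their median was -0.26 and the camera adjusted p 0.00018 (adjusted p 0.0492 with an estimated correlation). Of the 3389 genes higher in WT MII than in WT FGO 3W, 802 were higher and 283 lower in CKO zygotes. Their median was 0.22 and the camera adjusted p 0.0122 (adjusted p 0.672 with an estimated correlation). This call ended for genes at least 4-fold higher. The other 9 of 12 such tests were not called.

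Because DHX36 binds and unwinds G-quadruplexes, genes with a G-quadruplex motif in the spliced transcript were compared with the others. At MII 3W, 713 of the 2779 genes with a motif were higher and 340 lower in CKO (25.7% and 12.2%), against 19.3% and 20% of the others, and the median changes were 0.36 and 0.0087. At zygote 3W 21.2% and 10% of motif genes were higher and lower, against 16.6% and 16.1%, and at FGO 4W 15% and 14.5%, against 12.3% and 19%. At FGO 3W it was 7.92% and 11.9%, against 9.43% and 12.2%, with medians of -0.23 and -0.13, and at GO 2W 8.35% and 7.84%, against 8.16% and 7.95%, with medians of -0.13 and -0.070. With GC content, length and expression in the model, the motif coefficient was -0.034, -0.013, 0.17, 0.26 and 0.13 from GO 2W to zygote 3W. At MII 3W its exact permutation p was 0.0571, where the smallest possible is 0.0286. Averaged over the 5 stages the coefficient was 0.10 (exact permutation p 0.0147, 0.117 adjusted over 24 tests), and it was 0.084 with p 0.0539 without WT FGO 3W replicate 1. It was called after adjustment without WT FGO 3W replicate 2 (0.13, adjusted p 0.00921) or WT GO 2W replicate 2 (0.12, adjusted p 0.0288). Without the 3 libraries rich in ribosomal RNA it was 0.053 with p 0.0731. By region it was 0.096 for 5' UTRs (adjusted p 0.0143), 0.11 for coding sequences (adjusted p 0.0703) and 0.097 for 3' UTRs (adjusted p 0.171), each by exact permutation. The 5' UTR value was 0.062 without the 3 libraries rich in ribosomal RNA (adjusted p 0.0479) and was not called without the 4 libraries in doubt (0.061, adjusted p 0.0685), without WT FGO 3W replicate 1 (0.082, adjusted p 0.0909) or without CKO FGO 3W replicate 1 (0.095, adjusted p 0.0552). Without the 3 libraries rich in ribosomal RNA the coding sequence and 3' UTR values were 0.065 and 0.038, and without the 4 in doubt 0.068 and 0.026. In CKO MII replicates 2 and 3 and CKO zygote replicate 1 the 5' UTR coefficient was 0.203, 0.204 and 0.201, and between -0.0179 and 0.0464 in the other CKO MII and zygote libraries.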

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

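The tests of libraries rich in ribosomal RNA, of swapped labels and of 1 library carrying the Dhx36 rise were chosen only after those results were seen.

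Ribosomal protein transcripts were higher in CKO MII oocytes, where their list differed in its change from FGO 3W by 1.83 (adjusted p 9.25e-27, and 0.0595 with an estimated correlation). Libraries rich in ribosomal RNA do not account for it, since the median change was 1.27 without the 3 of them. A gain of short transcripts does not account for all of it. The list median of 1.41 lay at percentile 100 of 10000 random lists matched on transcript length and expression. Their median was 0.305 and their upper bound, set beforehand as a percentile, was 0.541. The median of all genes was 0.133, so genes of like length and expression rose too. Genes of random lists need not move together, so the percentile is not a p-value for this list. If transcripts lower in WT zygotes than in WT fully grown oocytes stay higher, the list should hold many of them. This prediction was met, as 92.6% of the list was at least 2-fold lower in WT zygotes than in WT FGO 4W (15.8% of all tested genes). The fall was already present in WT MII, where the list's mean log2 CPM lay between 2.75 and 2.84, against 6.64 to 6.82 in WT FGO 4W and 3.52 to 3.74 in WT zygotes. The share uses WT libraries only, so it cannot tell how the CKO level arose. Of all genes lower in WT zygotes than in WT FGO 4W, 1220 were higher and 329 lower in CKO MII. Of those lower in WT MII than in WT FGO 3W, 696 were higher and 1349 lower in CKO zygotes. Slower loss, a different poly(A) tail length at capture and a different maturity of the oocytes remain open and were not tested.

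Some genes were on in one genotype (at least 2 CPM in every library) and off in the other (under 0.1 CPM in every library). These were 16 at GO 2W, 59 at FGO 3W (with 2 libraries per group), 23 at FGO 4W, 12 at MII 3W and 2 at zygote 3W. Among GO 2W, FGO 3W and FGO 4W, 18 genes were on or off between WT groups and 55 between CKO groups. Of the 88 on or off between genotypes at those stages, 12 were also on or off between WT groups. Strain variants that reach neighbouring genes of different families would cluster in the genome. But 10.4% of the genes on or off between genotypes had another of a different family within 1 Mb, under the 95th percentile of random draws (19.8%). Variants that each switch a single gene need not cluster, so this share cannot test them. Of the 96 genes on or off between genotypes, 13 switched at several stages, and 8 of these (61.5%) switched in opposite ways. For those 8 a fixed switch by the deletion of Dhx36 is argued against. Genes that met the cut-offs at 1 stage only cannot test this. Some of them, such as Sohlh1, Dio3 and Abca9, changed in the same direction at all 5 stages. Reads shared between copies cannot be told apart from a change of each gene. Of the on or off genes 47.9% had a tested gene of the same symbol stem, between the bounds set beforehand. Strain variants that each switch a single gene remain open. So do those confined to the cluster of a single family, whose copies were not counted as neighbours. Differences between animals or litters also remain open, as no label gives them.

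Dhx36 counts were not lower in CKO-labelled libraries. The rise at MII 3W was not carried by 1 library alone, as it was 1.03 without CKO replicate 1 (adjusted p 0.0269, between 2.88e-24 and 0.0472 over its alternatives), but an exact permutation of the libraries gave p 0.257, and the CKO libraries lay between 338.3 and 3226 CPM, 1 of them below all WT libraries (397.3 to 429). Genotype labels swapped within a stage do not account for it, as 0 stages held both a WT and a CKO library nearer the other genotype and principal component 2 separated WT (-76.5 to -47.5) from CKO (21.2 to 79) in all 29 libraries. The only library nearer the other genotype was CKO zygote replicate 1, the richest in ribosomal RNA, and a swap of the genotypes at all stages together remains open. Transcripts that keep their other exons after a deletion could still be counted, which was not tested because the labels do not name the exons.

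A library far from the others was seen in 9 of the 91 values tested in the 4 CKO MII libraries. Chance gives about 1 in 20 for independent values, but these all come from the same 4 libraries. The gap to the nearest library over the range was 0.942 for the share of counts of mt-Rnr2, a mitochondrial ribosomal RNA (0.978% in replicate 3). It was 0.927 for Defa29, 1 for Defb8, 0.901 for Raet1d, 0.934 for Slamf7, 0.852 for Npm2, 0.875 for Lhx8, 0.941 for Uqcrh and 0.873 for Hsp90b1. For all of these but Defb8 the library apart was again replicate 3, where Rn18s-rs5 took 21.9% of the counts. Defb8 was at 0.0594 CPM in replicate 2 and at 0 in the others.

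The CKO change differed in 364 genes between GO 2W and FGO 3W, with differences of 9.83 for Pramel27, 9.69 for Gpat3, 8.999 for Xdh, -14.20 for Dcpp2 and -11.68 for Fermt1. Between these stages WT levels changed too, by -8.35 for Pramel27, -8.24 for Xdh and 7.88 for Dcpp2. Fermt1's call ended without CKO FGO 3W replicate 1 or 2. Without WT FGO 3W replicates 1 and 2 and CKO FGO 3W replicates 1 and 2 in turn the count was 210, 241, 201 and 189. Between FGO 3W and FGO 4W 592 genes differed (306, 305, 298 and 302 without those libraries in turn), among them Septin9 (10.23, not called without CKO FGO 3W replicate 1) and Pramel27 (-14.63). Between FGO 3W and MII 3W 3205 differed (1648, 1708 and 1529 without WT FGO 3W replicate 2 and CKO FGO 3W replicates 1 and 2), among them Dcpp2 (11.02), Gulp1 (-9.68), Xdh (-9.67) and Tox3 (-9.17). Between MII 3W and zygote 3W 3415 differed (5164 without CKO zygote replicate 1), among them Cdc5l (9.68), Gulp1 (6.24), Pip5k1b (6.03), Myo15b (5.59), Pcp4l1 (-9.17) and Btn1a1 (-7.61).

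The change of a list differed between stages in 8 of 80 tests, and in 0 with an estimated correlation. Between FGO 3W and FGO 4W these were the zygotic genome activation genes (median difference 0.50, adjusted p 0.00298), the ribosomal protein genes (0.46, adjusted p 0.000248) and the RNA polymerase II genes (0.31, adjusted p 0.00167). Between FGO 3W and MII 3W, besides the ribosomal protein genes, they were the oxidative phosphorylation genes (1.66, adjusted p 2e-20) and the RNA polymerase II genes (0.48, adjusted p 0.00298). Between MII 3W and zygote 3W they were the ribosomal protein genes (-0.43, adjusted p 0.000711) and the oxidative phosphorylation genes (-0.54, adjusted p 7.59e-05).

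Other splits of the same libraries were counted. At MII 3W 1 of the 35 splits, the real one, gave as many called genes (7172, highest other 5032). This share lies under 0.05, the bound set beforehand, and is the smallest that 35 splits allow. Such splits cannot tell genotype from a litter or batch shared by the libraries of a genotype. As many called lists came from 9 of the 35 (real value 3, highest other 5), so for the number of lists chance is not excluded. Of 80 drawn regroupings of MII 3W and zygote 3W, the real one included, 5 gave as many genes with a different change, the real one among them (real value 3415, highest other 8499), so chance is not excluded there. Of these 5, 2 exchange the genotypes within one stage, which turns the difference into a sum of both changes. Without such regroupings 3 of 78 gave as many, the real one again included (highest other 3605), so the share lies above or below 0.05 by whether such regroupings are counted. At GO 2W (2985, highest other 0), FGO 4W (5782, highest other 10), zygote 3W (5881, highest other 523) and for WT MII to WT zygote (7396, highest other 1) the 10 splits are too few for a share under 0.05.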

How the results depend on the processing

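The settings with 1 dispersion, without the 3 libraries rich in ribosomal RNA and without the 4 libraries in doubt, the leave-one-out list tests, the alternatives by region of the transcript and those of the stage correlation were chosen only after the results were seen. Counts stayed within 1.5 times under RLE size factors and the stricter filter (1512 higher and 1472 lower at GO 2W). With a replicate block 1264 genes were higher and 1071 lower at GO 2W, 1457 and 1710 at FGO 3W, 2108 and 2761 at FGO 4W, 3479 and 3052 at MII 3W and 2355 and 2541 at zygote 3W. With 1 dispersion for all genes FGO 3W gave 3538 higher and 3317 lower, the changes differed in 699 genes between GO 2W and FGO 3W and 1108 between FGO 3W and FGO 4W, and 538 changed from WT GO 2W to WT FGO 3W; with no filter these last counts were 639, 1005 and 530, and with DESeq2 676, 1115 and 578. The mean stage correlation was 0.181 with no filter, 0.294 with DESeq2 and 0.245 without the 4 libraries in doubt. With each stage fitted alone GO 2W gave 3520 higher and 2827 lower, FGO 3W 3860 higher and zygote 3W 1112 and 988, and Dhx36 at FGO 4W was called at 0.38. limma on log2(FPKM + 1) gave 2640 higher at GO 2W, 3207 higher at FGO 3W, 2018 lower at MII 3W and 2035 higher at zygote 3W; with 0.1 as pseudocount 909 were lower at GO 2W and 1205 at FGO 3W; with no filter on FPKM 3096, 4441 and 4478 were higher at GO 2W, FGO 3W and FGO 4W (at the last 2, 1671 and 2705 lower), 1836 lower at MII 3W and 1864 higher at zygote 3W. Called lists numbered 20, and 0 with an estimated correlation and 33 by fry, which ended 2 of the 20 calls. Of the 484 named-gene calls, as far as each setting tested them, 12 ended with a replicate block, 10 with no filter and 8 with each stage fitted alone, and leaving out 1 library at a time ended a call 217 times. Without the 3 libraries rich in ribosomal RNA MII 3W gave 3431 and 3042 and zygote 3W 3488 and 3949. Without the 4 in doubt MII 3W gave 3699 and 3258. At zygote 3W this left only CKO replicate 2 in its group, so zygote values without the 4 rest on that library. The G-quadruplex coefficient was 0.096 (p 0.151) without covariates, 0.053 (p 0.0731) without the 3 libraries rich in ribosomal RNA and 0.046 (p 0.116) without the 4 in doubt, and its unadjusted p was 0.000299 with the 2-tetrad motif (0.040) and 0.0183 with the longest transcript (0.099), all by exact permutation. By region, with p adjusted over 24 tests, the 5' UTR coefficient was not called without WT FGO 3W replicate 1 (0.082), CKO FGO 3W replicate 1 (0.095) or the 4 libraries in doubt (0.061), and that of coding sequences was called without WT GO 2W replicate 2 (0.12), WT FGO 3W replicate 2 (0.13) or CKO zygote replicate 3 (0.12). Reversed were Dhx36 at GO 2W (-0.050 without CKO replicate 3) and in zygotes (-0.14 without CKO replicate 1, -0.15 without the 3 and -0.31 without the 4 libraries), Defb8, CKO effect, MII 3W against zygote 3W (-1.86 without CKO zygote replicate 2, where leaving out any other library of these stages gave 6.58 to 9.31), and without the 4 libraries Irf3, CKO against WT, zygote 3W (-0.0087) and Cd74, CKO against WT, zygote 3W (-3.97). Leaving out 1 library at a time gave, higher and lower, 941 to 1358 and 722 to 1102 at GO 2W, 828 to 984 and 838 to 1333 at FGO 3W, 1883 to 2184 and 2428 to 2689 at FGO 4W, 3175 to 4245 and 2558 to 3159 at MII 3W, and 2213 to 3123 and 2305 to 3401 at zygote 3W. The genes whose change differs ranged over 189 to 311, 298 to 598, 1529 to 4097 and 2646 to 5164, those changed between WT stages over 82 to 216, 8468 to 10591 and 6137 to 7997, called lists over 15 to 22 and trajectory lists over 2 to 4. Dhx36 ranged over -0.050 to 0.22, 0.16 to 0.73, 0.27 to 0.37, 1.03 to 2.15 and -0.14 to 0.69 from GO 2W to zygote 3W, and the G-quadruplex coefficient over 0.084 to 0.13 for the transcript, 0.082 to 0.11 for 5' UTRs, 0.092 to 0.13 for coding sequences and 0.076 to 0.12 for 3' UTRs. Apart from counts of smaller sets of libraries, the cause of these changes was not tested. The spike-in alternatives could not be run, and at this depth 2-fold changes were called in at most 38.8% of simulated changed genes.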

Other observations

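A group of genes beyond those above was lower in CKO at all 5 stages. The X-linked lymphocyte-regulated genes Xlr3b, Xlr3c and Xlr5c, chromatin-associated germ-cell genes that lie within chromosome X from 73192150 to 73293863, were lower by between -4.93 and -1.67, Xlr3b from 20.6 CPM (SD 2.85) to 1.98 (SD 0.179) at FGO 4W. A read of one of these copies may be counted for another, which was not measured. Nfil3, a basic leucine zipper repressor gene, was lower by -1.67, -1.83, -2.05, -1.36 and -2.14 from GO 2W to zygote 3W, from 241.2 CPM (SD 6.25) to 54.8 (SD 18.5) in zygotes. Ifitm3, an interferon-induced membrane protein gene, was lower by between -3.48 and -1.50. The guidance genes Sema3e and Sema6a were lower by between -3.27 and -1.70. Rbms1, which encodes an RNA-binding protein, was higher by between 4.48 and 5.74, from 0.810 CPM (SD 0.491) to 43.5 (SD 4.1) at FGO 4W. Dio3, the thyroid hormone-inactivating deiodinase gene, was higher by between 4.30 and 7.07. These genes were chosen after their values were seen.

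Calls were shared between neighbouring stages more than independent stages would give. GO 2W and FGO 3W shared 902 higher genes (131 by independence) and 857 lower genes (134), while 63 went opposite ways (267). MII 3W and zygote 3W shared 1567 higher (577) and 1128 lower genes (400), while 432 went opposite ways (961).

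The share of Rn18s-rs5 lay between 1.61% and 5.59% in the WT libraries and at most at 6.81% in the CKO libraries other than CKO MII replicates 2 and 3 and CKO zygote replicate 1. Principal component 2 (14.2% of the variance) separated the genotypes in all 29 libraries, with WT between -76.5 and -47.5 and CKO between 21.2 and 79. Replicates of a group correlated at 0.902 to 0.984 over 29 pairs, and WT with CKO libraries of a stage at 0.9 to 0.951 over 43 pairs, in log2 CPM across genes. The slope of the CKO change on log2 transcript length was -0.12 at MII 3W (exact permutation p 0.0286, the smallest possible) and -0.038 as a mean of the 5 stages (exact permutation p 0.0113).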
